A study of Homo sapiens with 9 samples.

How the data were processed

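RNA from HEK293 cells, a line derived from human embryonic kidney, was measured on 9 Affymetrix arrays, 3 for each of 3 groups. The deposited table holds 1 linear intensity per probe set and array. The intensities were made with MAS5, per the submitters' processing notes, and the version is not given in the sources used here. MAS5 gives each probe set a signal from its perfect-match and mismatch probes and scales each array to a common mean. In these values the mean of the non-control intensities between percentiles 2 and 98 lay between 1493.6 and 1495.3 on all 9 arrays, so the deposited scaling was kept. The table has 54675 probe sets, of which 62 are Affymetrix controls. Detection calls were not used here. The number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

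Of the 54613 other probe sets, 41091 carried 1 gene symbol in the platform annotation, 1801 carried several and 11721 had none, and only those with 1 were named. Symbols were updated by gene identifier through a RefSeq table, and 54 probe sets kept the annotation's symbol. No coordinates are printed because no genome build goes with the values. Values were used as log2(value + 16), and fold changes are on that scale, which understates the change of dim probe sets. Probe sets with a mean log2 value under percentile 40 were left out, and 32768 were tested. A gene was represented by its probe set with the highest mean, which gave 14018 genes.

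One limma model (version 3.58.1, R 4.3.3) with empirical Bayes moderation and a variance trend was fitted to all 9 arrays, without the replicate number. Tests were two-sided with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The contrasts were each mutant against wild type, one mutant against the other, and the mean of both mutants against wild type. Of 17 gene lists, those with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and with fry. Camera compares a list with the other genes, while fry tests whether its genes move, on balance, one way and compares it with no other genes. The lists held 505 genes, of which 434 were tested and 39 had no probe set naming them alone. Values per array were compared with two-sided exact permutation tests. With 3 arrays against 3 the smallest exact p is 0.1.

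The rule for named genes was set before the data were examined, as were the contrasts, lists and alternative settings. The rule took SFTPC, HSPA5, DNAJB9, DNAJC10, HERPUD1, HSP90B1, DDIT3, ATF4, XBP1 and SEL1L. For each mutant against wild type it took the 10 largest rises and 10 largest falls among genes past the threshold whose mutant arrays all lay on one side of the wild-type arrays, and 5 each way between the mutants. From each list it took the 4 members with the smallest adjusted p, or the 2 largest changes where no member passed.

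The model was tested on simulated values with the means and spreads of the 32768 probe sets, 100 of them changed 2-fold and 100 changed 4-fold in both mutants. For LQ against wild type it recovered 9.0% of the 2-fold and 53.0% of the 4-fold changes, with 7 false calls. For Ex4 against wild type it recovered 10.0% and 53.0%, with 3 false calls. The simulation left out correlated differences between arrays. The alternatives were pseudocounts of 1 and 64, quantile normalization, centring each array on its median, no filter and a filter at percentile 60, no variance trend, only the arrays compared, the replicate number as a block, array weights, each array left out in turn, a 2-fold minimum, and for lists the estimated correlation and the mean of a gene's probe sets. The effect of the replicate block and of the others is given after the results.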

Results

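The series asked how HEK293 cells respond at the transcript level to misfolded surfactant protein C, a small hydrophobic protein made as a proprotein by alveolar type II cells of the lung. Cells were transiently transfected with wild-type protein (WT), a form lacking exon 4 (Ex4) or a form with the L188Q substitution (LQ), with 3 arrays per group. WT-transfected cells were the control. Array medians were 506.4 to 524.4 on the WT arrays, 316.1 to 434.3 on the Ex4 arrays and 303.9 to 371.8 on the LQ arrays, although trimmed means lay between 1493.6 and 1495.3. The median log2 value was 0.54 lower in both mutants than in WT (exact permutation p = 0.012 over 84 splits, the smallest they can give). No untransfected or empty-vector group was analysed here. Between arrays the correlation across tested probe sets was 0.842 to 0.959, and no 2 arrays were identical. Ex4 replicate 1 had a mean correlation of 0.906 with its own group and 0.911 with WT, while Ex4 replicates 2 and 3 had 0.926 and 0.927 with their own group and 0.871 and 0.864 with WT. The ratio of 3' to 5' signal, a sign of RNA integrity, was 1.31 ± 0.11 in WT, 1.12 ± 0.14 in Ex4 and 1.07 ± 0.016 in LQ for GAPDH (SD, n = 3). For ACTB it ran the other way, at 1.13 ± 0.12, 1.35 ± 0.18 and 1.18 ± 0.041. Both mutants together differed from WT for GAPDH (exact permutation p = 0.024, adjusted 0.040) and not for ACTB (exact permutation p = 0.23). The signal of the spike control BioDn was 48359 ± 8044 in WT, 33799 ± 8452 in Ex4 and 24379 ± 1823 in LQ (SD, n = 3), and both mutants together differed from WT (exact permutation p = 0.024, adjusted 0.040).

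SFTPC, the transfected gene, has 5 probe sets, called here A to E in the order in which the plot of SFTPC signal shows them from left to right with their identifiers. On probe set E the signal was 188520 ± 37483 in WT, 139947 ± 38236 in Ex4 and 122529 ± 5745 in LQ (SD, n = 3). On probe set C it was 192369 ± 42324 in WT and 115724 ± 9323 in LQ, but only 914.4, 39.1 and 28.7 on Ex4 replicates 1, 2 and 3. The fitted log2 change of Ex4 against WT on probe set C was -10.49 ± 0.83 (SE, limma adjusted p = 0.00037). Ex4 replicates 2 and 3 lay below their array medians there and Ex4 replicate 1 above its own, so the size is not well measured, with -10.85 at a pseudocount of 1, -9.81 at 64 and -11.90 without Ex4 replicate 1. On probe set A the change was -3.11 ± 0.17 (adjusted p = 8.9e-06). Whether these probe sets lie in the deleted exon was not analysed here. LQ was lower than WT on probe set A, with a log2 change of -0.73 ± 0.17 (adjusted p = 0.033). On B, D and E its log2 change was -0.76 ± 0.21, -1.83 ± 0.54 and -0.60 ± 0.21 (adjusted p = 0.051, 0.061 and 0.087). On C it was -0.71 ± 0.83 (adjusted p = 0.59). The SE pools the spread within every group, and on C the Ex4 arrays spread most on the log2 scale. WT (158962 to 239964) and LQ (108292 to 126185) did not overlap on C. The adjusted p there cannot show that LQ was unchanged. For Ex4 the log2 change was -0.65 ± 0.21 on B, -0.82 ± 0.54 on D and -0.45 ± 0.21 on E (adjusted p = 0.11, 0.37 and 0.20). The lower SFTPC signal in LQ depended on the scaling. After quantile normalization the LQ change was -0.18 on A and -0.19 on B (adjusted p = 0.36 and 0.28), and with each array centred on its median -0.14 and -0.18 (adjusted p = 0.65 and 0.62). For Ex4 the change on B became -0.34 and -0.17, and on E -0.11 and 0.04, while A kept its call at -2.84 and -2.62.

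**Figure D1:**
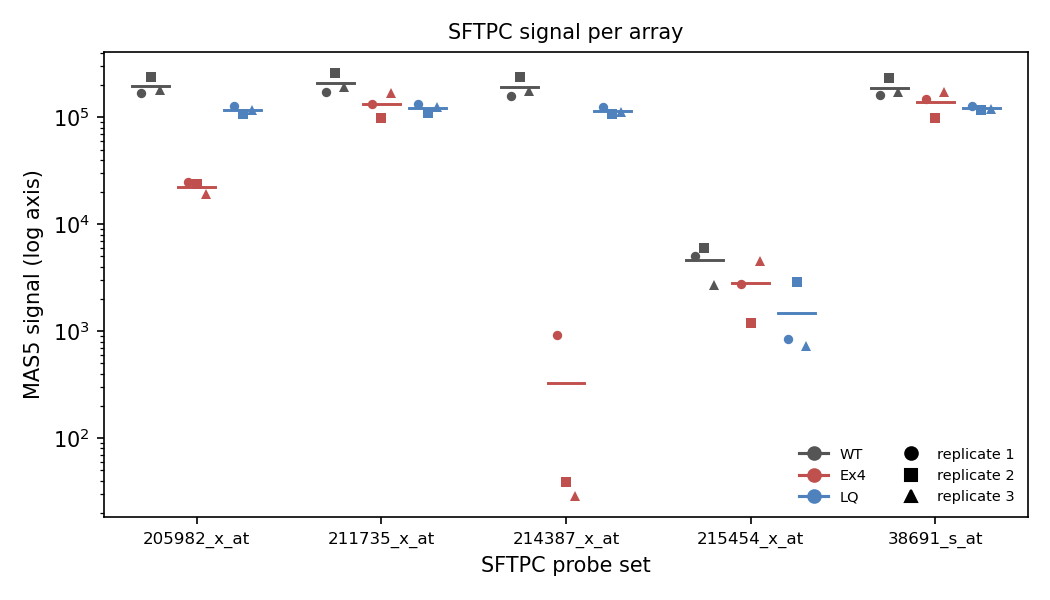
MAS5 signal (log axis) of the 5 SFTPC probe sets, A to E from left to right, on each array, with bars at the group means and symbols for replicates. On C the Ex4 arrays lie between 28.7 and 914.4, far below the WT and LQ arrays.

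Ex4 against WT asked which transcripts change with the deletion. Among 14018 genes none passed the threshold by limma on its representative probe set (3812 at an unadjusted p under 0.05), and 6 named genes of protein folding and degradation in the endoplasmic reticulum (ER) had positive changes. HSPA5, the main ER chaperone of the HSP70 family, had a log2 change of 0.79 ± 0.17 (SE, adjusted p = 0.077). HERPUD1, a component of ER-associated degradation, had 0.95 ± 0.19 (adjusted p = 0.076). DNAJB9, an ER cochaperone, had 0.94 ± 0.22 (adjusted p = 0.077), and HSP90B1, the ER member of the HSP90 family, had 0.94 ± 0.22 (adjusted p = 0.077). DNAJC10 had 0.92 ± 0.26 (adjusted p = 0.088) and SEL1L 0.63 ± 0.16 (adjusted p = 0.080). Other probe sets of these genes differed, with -0.02 on the second of HSP90B1, 0.37 on the second of HSPA5, -0.19 and -0.42 on the other 2 of SEL1L, and -1.28 to 1.27 on the other 4 of DNAJC10. HSPA5, HERPUD1, DNAJB9, HSP90B1 and SEL1L were above all WT arrays on each of 3 Ex4 arrays, and DNAJC10 on 2 of 3. ATF4, DDIT3 and XBP1, transcription factors of the unfolded protein response, had log2 changes of -0.31, -0.20 and -0.03 (adjusted p = 0.29, 0.53 and 0.94). The second XBP1 probe set had -0.765 (adjusted p = 0.20). With each array centred on its median the representative values of ATF4, DDIT3 and XBP1 became 0.18, 0.29 and 0.46 and did not pass (adjusted p = 0.57, 0.33 and 0.29). HSPA5, HERPUD1, DNAJB9 and HSP90B1 then passed, at 1.27, 1.44, 1.43 and 1.43, as did DNAJC10 at 1.41 and SEL1L at 1.115 (adjusted p = 0.015 and 0.014). After quantile normalization HSPA5, HERPUD1, DNAJB9 and HSP90B1 did not pass (adjusted p = 0.093, 0.087, 0.095 and 0.11), nor did DNAJC10 and SEL1L (0.13 and 0.12). HSPA5, HERPUD1, DNAJB9 and HSP90B1 passed in 2 of the 9 fits without 1 array, those without Ex4 replicate 1 (adjusted p = 0.014, 0.0035, 0.0042 and 0.036) and without WT replicate 1 (0.0054, 0.013, 0.029 and 0.0015). Over the 9 fits their highest adjusted p was 0.23, 0.23, 0.24 and 0.23. DNAJC10 and SEL1L passed in the same 2 fits, with highest adjusted p = 0.26 and 0.24.

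Of 32768 probe sets, limma called 4 in Ex4 against WT, 2 higher and 2 lower, and 8150 had an unadjusted p under 0.05. Among 14018 genes it called 0, with 3812 at an unadjusted p under 0.05. The 2 lower probe sets were those of SFTPC. The 2 higher were named after their values were seen. They were 1 of the probe sets of TFAM, a mitochondrial transcription factor, with a log2 change of 1.39 ± 0.15 (adjusted p = 0.0098), and a probe set with no single gene name, with 1.13 ± 0.14 (adjusted p = 0.028). The count was 4433 without Ex4 replicate 1 (1415 higher, 3018 lower), 3679 without WT replicate 1, and 2 without WT replicate 2, without Ex4 replicate 3 and without LQ replicate 2, each left out in turn. It was 5287 with array weights. In the fits with a count of 2, and with only the arrays compared, 0 probe sets passed higher. Both the TFAM call and the unnamed one were lost there. Centring each array on its median gave 4824 higher and 282 lower, and quantile normalization 6 and 3. The median log2 change over tested probe sets was -0.12 for Ex4 and -0.15 for LQ as scaled, 0.02 and 0.04 after quantile normalization, and 0.37 and 0.44 after median centring.

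In Ex4, 6 of 16 tested lists lay higher than other genes by camera, and none of their members passed over all probe sets. For each of these 6 lists the adjusted p = 0.52 with an estimated correlation, and by fry it was 0.17 or more. Brighter probe sets fell less, as the median log2 change of Ex4 was -0.27 with no filter, -0.12 at percentile 40 and -0.02 at percentile 60. The WT means of the ER chaperone, ER-associated degradation and cell cycle lists were 12.9, 12.4 and 13.0. The medians of tested probe sets on the WT arrays were 10.3 to 10.4. A test against other genes cannot tell a rise of such bright lists from this trend. In the ER chaperone list 20 of 33 members had positive changes, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0031). ER-associated degradation had 21 of 31 positive and 4 higher adjusted over the list alone (0.045 by camera, 0.052 with the replicate number as a block and 0.091 with the mean of a gene's probe sets), with EDEM3 at 0.96. The secretory pathway list had 33 of 48 positive and 2 higher adjusted over the list alone (0.016), with ARFGAP3 at 2.65-fold and CREB3L1 at a log2 change of -1.55, whose size is not measured because it lay below the array median on all 3 Ex4 arrays. Proteasome subunits had 25 of 33 positive and 0 adjusted over the list alone (0.040), with PSMC6 at 0.68 and PSMA3 at 0.60. The cell cycle list had 26 of 40 positive and 0 adjusted over the list alone (0.030), with CDK1 at 2.65-fold and CENPE at 2.58-fold. The CDK1 signal was 13054.5 on WT replicate 1, near the 13338.1 of Ex4 replicate 1, and 4247.1 and 4563.3 on the other WT arrays. The CENPE signal was 5138.3 on WT replicate 1 and 701.8 and 832.7 on the other WT arrays, and its log2 change was 2.27 without WT replicate 1 (adjusted p = 0.0080). The interferon list had 29 of 30 positive and 5 higher adjusted over the list alone (1.2e-07), with IFNB1 at 2.35 and IFI44 at 1.98. IFNB1 and IFI44 lay below the array median on 2 of 3 WT arrays, and had 3.33 and 2.63 without WT replicate 3. WT replicate 1 was the lowest of the 9 arrays for 24 of the 30 members, and the mean difference between Ex4 and WT was 1.09 with it (exact permutation p = 0.30) and 0.55 without it. After quantile normalization the ER chaperone list had adjusted p = 0.20, ER-associated degradation 0.72, the secretory pathway 0.53, proteasome 0.91, cell cycle 0.73, the interferon list 2.1e-07 and the inflammatory list 0.042. Without WT replicate 1 it was 0.25 for ER-associated degradation, 0.21 for the secretory pathway and for the cell cycle, 0.56 for proteasome and 0.048 for ER chaperones and interferon. The call of ER-associated degradation was also lost without WT replicate 3, Ex4 replicate 2 or Ex4 replicate 3, that of proteasome without Ex4 replicate 2 or 3, that of the secretory pathway without Ex4 replicate 3 and that of the cell cycle without Ex4 replicate 2. With a filter at percentile 60 the adjusted p was 0.22 for ER-associated degradation, 0.11 for the secretory pathway, 0.21 for proteasome and 0.20 for the cell cycle. Without a variance trend ER-associated degradation had 0.051, and with array weights proteasome had 0.15.

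The other lists did not pass in Ex4. The adjusted p was 0.32 for the PERK-ATF4 branch (CTH at 0.79, VLDLR at -0.67), 0.11 for the heat shock response (HSPA6 at 1.16, CHORDC1 at 0.64) and 0.99 for apoptosis and p53 targets (BCL2 at -0.96, TNFRSF10A at -0.95, 2 higher and 1 lower adjusted over the list alone). It was 0.11 for inflammatory cytokines, with CXCL8 at 2.82-fold and CXCL10 at 2.61-fold and 1 higher adjusted over the list alone, and 0.50 for oxidative stress, with MT1E at -1.05 and NQO1 at -0.96 and 1 higher adjusted over the list alone. No member of the other lists tested in this paragraph passed adjusted over the list alone. It was 0.99 for cholesterol synthesis (MVK at -0.75, IDI1 at 0.63), 0.38 for immediate early genes (NR4A1 at -0.90, ZFP36 at 0.80) and 0.43 for hypoxia (SLC2A1 at -1.10, CA12 at -0.85). It was 0.36 for alveolar type II markers (CLDN18 at -1.39, NKX2-1 at -1.14) and 0.21 for fibroblast markers (COL1A2 at -1.02, COL1A1 at -0.52). Blood cell markers had 4 tested members and no test, with CD3D at -1.08 and CD79A at -0.79 and 1 lower adjusted over the list alone. The heat shock response was called higher with median centring (0.027), with no filter (0.027), with the mean of a gene's probe sets (0.036), without WT replicate 2 (0.019) and without Ex4 replicate 1 (0.025). Inflammatory cytokines were called higher with no filter (0.014), with the mean of a gene's probe sets (0.0078), without WT replicate 3 (0.025) and without Ex4 replicate 3 (0.018). Without WT replicate 3 the PERK-ATF4 branch was called higher and fibroblast markers lower (0.047 each). Single arrays moved several values. CXCL10 had 68.8 on WT replicate 1 and 576.4 and 798 on the other WT arrays, with a log2 change of 0.37 without WT replicate 1 and 2.01 without WT replicate 3. COL1A2 had 0.05 without Ex4 replicate 2 and -1.66 without Ex4 replicate 1, ZFP36 1.60 without WT replicate 2 and NKX2-1 -1.79 without WT replicate 3. CLDN18 and CD3D lay below the array median on 2 of 3 Ex4 arrays. The test pointed up where the median was negative for the PERK-ATF4 branch, apoptosis and p53 targets, cholesterol synthesis and immediate early genes.

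LQ against WT asked the same of the substitution. Of the 6 named genes of ER folding and degradation, 5 rose. HERPUD1 was 2.40-fold higher (log2 change 1.26 ± 0.19, adjusted p = 0.015), HSP90B1 2.11-fold (1.08 ± 0.22, adjusted p = 0.026), DNAJB9 2.02-fold (1.01 ± 0.22, adjusted p = 0.030) and HSPA5 1.70-fold (0.77 ± 0.17, adjusted p = 0.033). SEL1L, an adaptor of the degradation complex, was 1.49-fold higher (adjusted p = 0.0495, and 0.13 after quantile normalization), and its other 2 tested probe sets had log2 changes of -0.41 and 0.44. DNAJC10 had a log2 change of 0.84 ± 0.26 on its representative probe set (adjusted p = 0.066), and its other 4 had 1.65, 0.86, -0.36 and -1.38 (adjusted p = 0.022, 0.067, 0.48 and 0.065). The second HSP90B1 probe set had -0.19 and the second HSPA5 probe set 0.13 (adjusted p = 0.69 and 0.75). HERPUD1, HSP90B1, DNAJB9 and HSPA5 each passed in 4 of the 9 fits without 1 array, and SEL1L in 2. All 3 LQ arrays were above all WT arrays for each of HERPUD1, HSP90B1, DNAJB9, HSPA5, SEL1L and DNAJC10. ATF4, DDIT3 and XBP1 had log2 changes of -0.13, 0.19 and -0.07 (adjusted p = 0.65, 0.53 and 0.84), although all 3 LQ arrays were above all WT arrays for DDIT3. ATF4 had 0.06 after quantile normalization. Median centring moved the 3 to 0.45, 0.77 and 0.51, and DDIT3 then passed (adjusted p = 0.015). The second XBP1 probe set had -0.87 as scaled (adjusted p = 0.12).

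**Figure D2:**
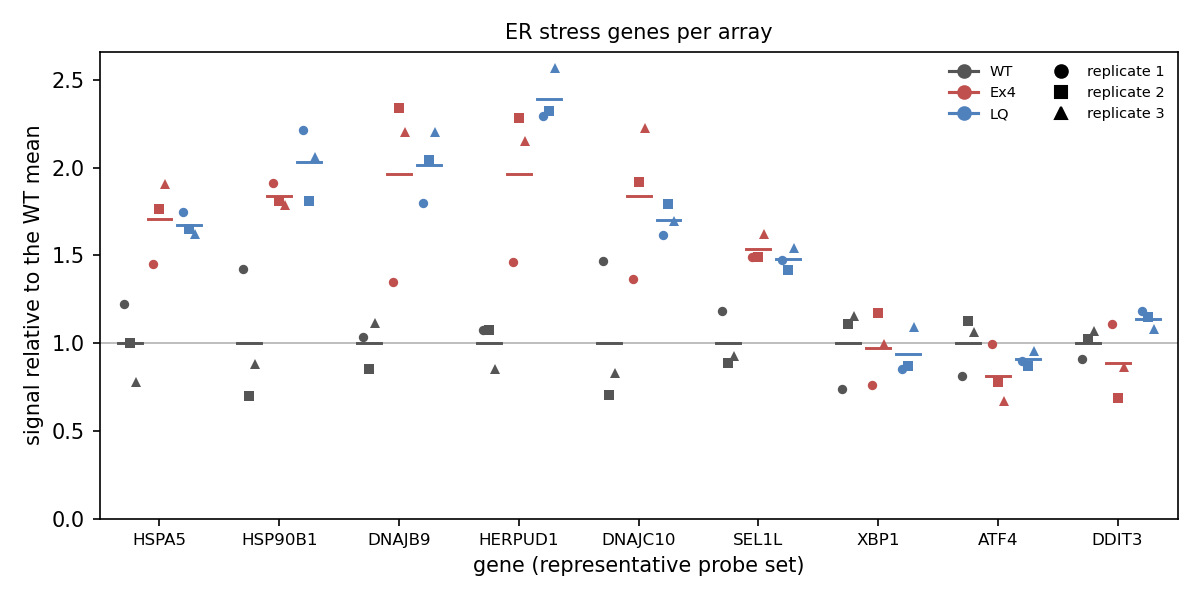
Signal of 9 genes on each array relative to the WT mean of the gene (linear axis), with bars at group means and symbols for replicates. HSPA5, HSP90B1, DNAJB9, HERPUD1 and SEL1L lie above all 3 WT arrays on every mutant array, while the LQ arrays lie within the WT range for XBP1 and ATF4.

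Among the largest fitted rises in LQ were AAGAB, a clathrin adaptor assembly factor, at 8.11-fold (log2 3.02 ± 0.62, adjusted p = 0.028), LCAT at 4.87-fold, MCOLN1, a lysosomal channel, at 4.74-fold, PARG at 4.44-fold, HECTD2 at 3.90-fold, RIF1 at 3.86-fold and DTX3 at 3.84-fold. AAGAB, LCAT, MCOLN1 and DTX3 lay below the array median on at least 1 WT array. DYNC2I1, ESRP1, an epithelial splicing regulator, and VAV1 rose from WT signals of 68.4 to 197.9, 23.6 to 389.1 and 76.3 to 129.9, below the array medians, so the size of their changes is not measured. H1-4, a linker histone, fell 42.9-fold (log2 change -5.42 ± 1.27, adjusted p = 0.035), and H2BC6 and H2BC12L, other histone genes, were 12.8- and 7.97-fold lower. Histone probe sets can share sequence between copies, so these copies are uncertain. On Ex4 replicate 1 the H1-4 signal was 35539, within the WT range of 27635 to 75258, and on the other two Ex4 arrays 328.2 and 459.4. In LQ the signal was 65.6 to 191.0 for H3C7, 124.9 to 273.7 for H3C11, 47.0 to 152.5 for GRIP2 and 25.5 to 100.5 for CCDC80, below the array medians, so the sizes of these falls are not measured. S1PR4, KCNS1 and PRX fell to 167.2 to 556.1, 142.9 to 1194.2 and 53.8 to 547.6, above the array median on at least 1 LQ array each. Without LQ replicate 1 the log2 change was -3.74 for KCNS1 and -2.06 for PRX, without LQ replicate 3 it was -2.27 for KCNS1, and none of these 3 values passed. MCOLN1 had 2.88 without WT replicate 2.

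Of 32768 probe sets limma called 2231 in LQ against WT, 1011 higher and 1220 lower. Among genes 517 were higher and 509 lower. Median centring gave 7934 higher and 518 lower, and quantile normalization 672 and 489. The count rested on most single arrays. It was 14, 10 and 8 without LQ replicate 1, 2 or 3, 33 and 46 without WT replicate 2 or 3, 4993 without WT replicate 1 and 4406 without Ex4 replicate 1. It was 442 without the variance trend, 4035 with only the arrays compared and 8580 with array weights. Of 52 named calls, 34 passed after quantile normalization and 50 after median centring, and 0 passed in all 9 fits without 1 array. All 52 kept their direction under both scalings and in those fits. In the fits without 1 array this was largely fixed by the choice of genes. The largest rises and falls were taken only where all LQ arrays lay on one side of all WT arrays. List members were taken by adjusted p. The calls lost after quantile normalization were those of SEL1L, H3C7, PRX, CRELD2, ERLIN1, EDEM3, CEBPG, SRP19, ARFGAP3, GOLGB1, HSPB8, PSMD9, IFIH1, SQSTM1, CDK1, IER2, KDM3A and CA12 (adjusted p = 0.051 to 0.13). Those lost after median centring were CA12 at -0.60 and COL1A1 at -0.38 (adjusted p = 0.18 and 0.30). Values here are of the representative probe set, and other probe sets of some genes went the other way. The same direction was seen on 1 of 2 others for AAGAB, 0 of 1 for HECTD2, 5 of 7 for RIF1, 2 of 4 for DTX3, 0 of 1 for ERLIN1, 0 of 1 for HSPB8, 2 of 5 for MCL1, 1 of 4 for SQSTM1, 2 of 3 for CDK1, 3 of 4 for CA12 and 3 of 4 for COL1A1.

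In LQ, 8 of 16 tested lists lay higher by camera, and with an estimated correlation none passed (adjusted p = 0.41 to 0.55 for these 8). In the ER chaperone list 7 of 33 members rose, 1 fell and 25 did not pass, with CRELD2 at 0.92 beside HSP90B1, DNAJB9 and HSPA5 (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.019). In ER-associated degradation 6 of 31 rose (6 higher and 1 lower adjusted over the list alone, 0.0066), among them HERPUD1, CRELD2, ERLIN1 at 0.95 and EDEM3 at 1.04. In the PERK-ATF4 branch 2 of 42 rose (2 adjusted over the list alone, 0.045). They were ATF3, a stress-induced transcription factor, at 0.90 and CEBPG at 0.78, while XPOT had 0.54 and VLDLR -0.80 without passing. In the secretory pathway list 3 of 48 rose, SRP19 at 0.61, ARFGAP3 at 1.21 and GOLGB1 at 1.27, and 0 did adjusted over the list alone (0.019); SEC11A had 0.44. Of proteasome subunits 1 of 33 rose, PSMD9 at 0.73, and 4 did adjusted over the list alone (0.049), with PSMA4 at 0.50, PSMC3 at 0.72 and PSMA3 at 0.62. The adjusted p with an estimated correlation was 0.50 for the ER chaperone, secretory pathway and proteasome lists, 0.47 for ER-associated degradation and 0.55 for the PERK-ATF4 branch. After quantile normalization it was 0.43 for ER chaperones and for the PERK-ATF4 branch, 0.30 for ER-associated degradation, 0.52 for the secretory pathway and 0.94 for proteasome. Without WT replicate 1 it was 0.11 for ER chaperones, 0.48 for the PERK-ATF4 branch and for proteasome, and 0.21 for the secretory pathway. The calls were also lost without LQ replicate 3 for the PERK-ATF4 branch and proteasome, without LQ replicate 2 for the secretory pathway and without Ex4 replicate 1 for proteasome. With a filter at percentile 60 the adjusted p was 0.13 for ER chaperones and for the secretory pathway, 0.060 for ER-associated degradation, 0.21 for the PERK-ATF4 branch and 0.25 for proteasome. With array weights it was 0.30 for the PERK-ATF4 branch and 0.23 for proteasome.

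Of the cell cycle list 6 of 40 members rose in LQ and 8 did adjusted over the list alone (camera adjusted p = 0.0020). The adjusted p = 0.41 with an estimated correlation and 0.30 after quantile normalization. MCM3 and CDC6, genes of DNA replication, rose by 0.82 and 0.97, AURKA by 0.80 and CDK1 by 1.43. For CDK1 the WT arrays differed, with 13054.5 on replicate 1 and 4247.1 and 4563.3 on the others, and LQ replicate 3 had 14100. By fry, which compares a list with no change and not with other genes, the cell cycle list had adjusted p = 0.033. It was the only list below 0.05 in LQ. Fry was run only in the deposited scaling, where array medians differed between WT and LQ, so it does not remove the limit for bright lists. Of the inflammatory list 2 of 22 rose, CXCL8, a neutrophil chemokine, at 1.92 and TNFAIP3 at 1.24, with 5 higher adjusted over the list alone (0.049). The adjusted p = 0.50 with an estimated correlation. CCL5 had 1.43 and PTGS2 1.07. This call was lost without any 1 of WT replicates 1 and 2, Ex4 replicates 1 and 2 and LQ replicates 1 and 3, with adjusted p = 0.24 without WT replicate 1. It was also lost with median centring (0.13), without a variance trend (0.078) and with array weights (0.23), and kept after quantile normalization (0.014). Of the interferon list 2 of 30 rose, DDX60 at 1.88 and IFIH1 at 1.63, with 4 higher adjusted over the list alone (1.5e-07, and 0.50 as the adjusted p with an estimated correlation). IFIT2 had 2.11 and IFI44 1.80, and without WT replicate 3 they had 2.99 (adjusted p = 0.042) and 2.45, while IFIT2 had 1.31 without WT replicate 1. The interferon list mean varied between WT arrays from 9.64 to 12.01 on the log2 scale, and LQ minus WT was 1.18 (exact permutation p = 0.30), or 0.63 without WT replicate 1.

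**Figure D3:**
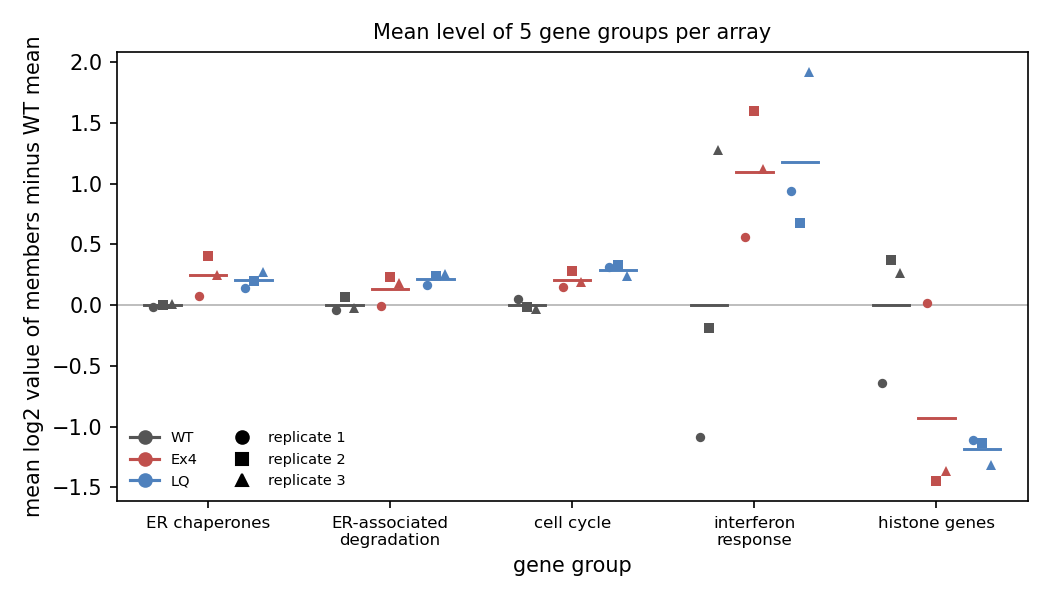
Mean log2 value of the members of 5 gene groups on each array minus the WT mean of the group (log2 units), with bars at group means and symbols for replicates. The interferon group spans 9.64 to 12.01 before subtraction within WT, and the histone group, chosen after its values were seen, lies within the range of the WT arrays on Ex4 replicate 1 and below it on the other mutant arrays.

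The other lists did not pass in LQ. Of apoptosis and p53 targets 5 of 28 rose and 6 higher and 2 lower passed adjusted over the list alone (camera adjusted p = 0.18). MCL1, an inhibitor of apoptosis, rose by 1.21, GADD45A 2.15-fold, PMAIP1 by 0.64 and BAK1 by 1.16. Of the heat shock response 1 of 24 rose, HSPB8 at 0.83, with 2 higher and 1 lower adjusted over the list alone (0.92), with HSPD1 at -0.45, DNAJB6 at 0.49 and HSPA1L at -1.64. HSPA1L lay below the array median on all 3 LQ arrays, so its size is not measured. Of the oxidative stress list SQSTM1, an autophagy receptor, rose by 0.75, with 3 higher and 4 lower adjusted over the list alone (0.72), with MT1H at -1.27, SLC30A1 at 0.79 and TKT at 0.74. Among immediate early genes IER2 rose by 0.73, with 1 adjusted over the list alone (0.14), with CCN1 at 0.68, ZFP36 at 1.33 and NR4A1 at -0.95. This list was called higher with no filter (0.015) and without WT replicate 2 (0.016), where ZFP36 had 2.13 (adjusted p = 0.022). Among hypoxia genes KDM3A rose by 0.82 and CA12 had a log2 change of -1.19 and passed, with 1 higher and 2 lower adjusted over the list alone (0.92, with a positive median and a negative mean), with SLC2A1 at -0.99 and MXI1 at -0.54. Of cholesterol synthesis genes none passed (0.85), with STARD4 at 0.56 and MVK at -0.54. Alveolar type II markers had none (0.70), with PGC at -0.88 and HOPX at -0.71. Of fibroblast markers COL1A1 passed with a log2 change of -0.96 (0.14), and COL1A2, FN1 and FBN1 had -1.31, -0.21 and -0.23. Without WT replicate 3 fibroblast markers were called lower (0.036). With median centring HSPD1, MVK, MXI1, FN1 and FBN1 turned to 0.14, 0.04, 0.04, 0.38 and 0.36, and FBN1 had 0.06 after quantile normalization. Blood cell markers had 2 lower adjusted over the list alone and none over all probe sets, with CD3D and HBB at LQ signals of 140.8 to 309.7 and 133.1 to 288.9. These lie below the array medians, so the sizes of their changes are not measured.

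LQ against Ex4 asked where the 2 mutants differ. Of 32768 probe sets 2 passed, both of SFTPC and both higher in LQ, with 1345 at an unadjusted p under 0.05. Of 14018 genes 0 passed by limma, with 588 at an unadjusted p under 0.05. HSPA5, DNAJB9, HERPUD1 and HSP90B1 differed by -0.02 ± 0.17, 0.07 ± 0.22, 0.31 ± 0.19 and 0.14 ± 0.22, which does not show that the mutants act alike. With median centring HSPA5 had 0.07, and without Ex4 replicate 1 DNAJB9 had -0.18. The heat shock list lay lower and apoptosis and p53 targets higher in LQ than in Ex4 (camera adjusted p = 0.0080 for each), with adjusted p = 0.66 and 0.29 with an estimated correlation. Adjusted over the list alone 1 heat shock gene was lower and 0 apoptosis and p53 genes passed by limma. Without Ex4 replicate 2 the heat shock list had adjusted p = 0.098, and with the mean of a gene's probe sets 0.065. ER-associated degradation, the PERK-ATF4 branch and the cell cycle list did not pass (0.088, 0.079 and 0.051), and were called higher in LQ with only the arrays compared (0.039 each) and in 4, 5 and 4 of the 9 fits without 1 array.

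Across 14018 genes, which are not independent replicates, the log2 changes of Ex4 and LQ against WT correlated with r = 0.858. Unchanged groups simulated against the shared WT arrays gave 0.547 on average over 100 draws. The covariance was 0.378 and the simulated one 0.0802. The simulation kept the 3 WT arrays shared, and did not hold differences between arrays that many genes share. Both mutants together against WT gave 3818 called probe sets, 1601 higher and 2217 lower. Among them HSPA5 rose by 0.78, HERPUD1 by 1.11, DNAJB9 by 0.98, HSP90B1 by 1.01, DNAJC10 by 0.88 and SEL1L by 0.60 on the log2 scale (adjusted p = 0.021, 0.014, 0.021, 0.020, 0.034 and 0.026). After quantile normalization DNAJC10 and SEL1L did not pass (adjusted p = 0.064 and 0.058). Of the 9 fits without 1 array, HERPUD1 passed in 7, HSPA5, DNAJB9 and HSP90B1 in 6, SEL1L in 3 and DNAJC10 in 2. The other probe sets had the same direction in 2 of 4 for DNAJC10, 1 of 2 for SEL1L and 0 of 1 for HSP90B1. The count was 25 and 34 without WT replicate 2 or 3, 309 without LQ replicate 3, 6331 without WT replicate 1 and 7229 without Ex4 replicate 1. It lay between 889 and 1313 without any of the other four arrays. Quantile normalization gave 1396 higher and 1005 lower, and median centring 9039 and 697. In this contrast 6 lists lay higher, those of ER chaperones, ER-associated degradation, the secretory pathway, proteasome, interferon and cell cycle (adjusted p = 0.0068, 0.011, 0.011, 0.035, 4.3e-08 and 0.0068), each with adjusted p = 0.53 with an estimated correlation. The limit given for bright lists holds here too. Without WT replicate 1 only the interferon list passed (0.034), and ER chaperones had 0.062. Without LQ replicate 3 the proteasome list did not pass. In the order above, the adjusted p after quantile normalization was 0.40, 0.45, 0.51 and 0.92 for the first 4 lists and 0.45 for the cell cycle, and with a filter at percentile 60 it was 0.067, 0.090, 0.090, 0.21 and 0.067. Proteasome had 0.20 with array weights. The inflammatory list did not pass (0.066) and was called higher after quantile normalization (0.016), with no filter (0.0038) and with the mean of a gene's probe sets (0.0047). The PERK-ATF4 branch did not pass (0.11) and was called higher with median centring (0.031) and with no filter (0.012).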

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

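The tests of material from WT, of transcript level, of cycling cells, of differences across groups and of variation within WT were chosen after the results were seen. The mutants differed from each other on 2 SFTPC probe sets, by 9.78 on probe set C and 2.39 on probe set A (log2, LQ minus Ex4), where the size on probe set C depends on the pseudocount. By camera the heat shock list lay lower and the apoptosis and p53 list higher in LQ (adjusted p = 0.0080 for each). Neither passed with an estimated correlation (adjusted p = 0.66 and 0.29), nor did the heat shock list with the mean of a gene's probe sets (adjusted p = 0.065). Of the 10 splits of those 6 arrays, 5 gave as many list calls as the real 2, the highest being 6, and 10 splits are too few for a share under 0.05. The real 2 probe sets compare with 0 at most in another split, 1 split counting the real one. Other groupings and the intensity and scaling tests were set before those results were seen. Groups of 3 arrays were not tested for outliers.

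Ex4 replicate 1 stood apart from the other Ex4 arrays. On a line from the LQ mean to the WT mean over 14018 genes it lay at 50.8%, and Ex4 replicates 2 and 3 at 1.24% and 1.92%. A wrong label or a large share of material from WT is argued against by probe set C, where the array had 0.475% of the WT signal. Its signal there was 914.4, against 39.1 and 28.7 on the other Ex4 arrays, so a trace of WT material is not excluded. The array intensity distribution is argued against, since after quantile normalization it still lay at 46.6%. A lower level of the transfected transcript stays open, because the ratio to the other Ex4 arrays on the bright SFTPC probe sets was 1.06 and those arrays differ from each other by more than that. On B and E Ex4 replicate 1 had 134379 and 149954, above replicate 2 (97630 and 97702) and below replicate 3 (169241 and 172184). The level did not order the Ex4 arrays as their positions do, but this rests on single arrays. No biological explanation was tested.

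Of 31 replication-dependent histone genes, chosen after their values were seen, 9 passed lower in LQ and 1 passed higher, H2AC6. The others did not pass, while 509 of all 14018 genes passed lower. H2BC12L, which also passed lower in LQ (limma adjusted p = 0.028), was not among the 31. Enrichment was not tested, and the pattern may belong to arrays more than to the groups. For fewer cycling cells, the cell cycle list mean was 0.293 higher in LQ (log2) and all LQ arrays were above all WT arrays. The limit given for bright lists holds for this mean too. After quantile normalization the list pointed up but was not called (camera adjusted p = 0.30). Fewer cycling cells are therefore not excluded. For array scaling, the median change of the genes that fell was -2.95 as scaled and -2.78 after quantile normalization. That normalization moved the LQ median over all tested probe sets only from -0.15 to 0.04. Genes picked for such falls could hardly lose them by it. The values show only that scaling differences of this size are too small for these falls. A difference between arrays that cuts across the groups had the values it needs, as Ex4 replicate 1 was 2.48 (median, log2) above the other Ex4 arrays on the genes that fell; these transcripts mostly lack a poly(A) tail, so RNA priming and culture both stay open.

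Interferon genes were higher in the mutants, which could be variation between arrays of one group. The WT arrays alone spanned 2.37 in the list mean, against 1.14 between both mutants and WT (log2, exact permutation p = 0.083), and without WT replicate 1 the difference was 0.59. Array scaling is argued against, since the difference was 1.25 after quantile normalization. A response to the mutant proteins stays open.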

How the results depend on the processing

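The alternatives and arrays left out were all chosen before the data were examined. SFTPC on probe set C passed with one direction in every setting, from -9.81 to -11.2, and from -9.71 to -11.9 without 1 array. The cause of the changes below was not tested except where a filter or fewer arrays state it. The Ex4 count was 9 with quantile normalization, 5106 with median centring, 2 with only the arrays compared and 5287 with array weights. The LQ count was 1161 and 8452 with the 2 scalings, 442 without a variance trend, 4035 with only the arrays compared, 8580 with array weights and 1464 with a 2-fold minimum. LQ against Ex4 gave 1 without a trend. Both mutants gave 2401 and 9736 with the scalings, 1520 without a trend, 9036 with weights and 2054 with a 2-fold minimum. Without 1 array the counts ranged from 2 to 4433 (Ex4), 8 to 4993 (LQ), 2 to 3 (LQ against Ex4) and 25 to 7229 (both).

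List counts fell with quantile normalization to 2 for each contrast with WT, with a percentile 60 filter to 2 (Ex4), 3 (LQ) and 1 (both), and with an estimated correlation to 0 in all 4 contrasts. The LQ lists were 5 with array weights, both mutants' lists 10 with no filter, and lists between mutants 4 with no filter, 5 with only the arrays compared and 1 with the mean of probe sets. Without 1 array they ranged from 2 to 8 (Ex4), 3 to 9 (LQ), 2 to 5 (LQ against Ex4) and 1 to 9 (both). The correlation was 0.787 with no filter and 0.886 at percentile 60, and 0.797 to 0.892 without 1 array. Named calls were 59, but 93 with median centring, 102 with array weights, 14 without a trend, and 1 to 96 without 1 array. Of 1459 values of named genes under the alternatives 1243 kept their direction and side of the threshold, and of 760 list results 635 did. Without 1 array 940 of 1332 values of named genes did and 296 lost their call, and of 576 list results 489 did. Values that stayed uncalled count as kept here. Only the 59 named calls could lose a call, so these shares overstate how stable the calls were. Blood cell markers had enough members for a test with no filter alone. DDIT3 in both mutants turned to 0.53 with median centring and passed (adjusted p = 0.036). The interferon list was called lower in LQ than Ex4 without LQ replicate 3 (adjusted p = 0.037) and higher without LQ replicate 2 (0.014), the lowest adjusted p without 1 array, and the highest was 0.61.

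Arrays with the same replicate number share only a number: the 9 correlations of their deviations ran from -0.083 to 0.19 and 4 were over 0.1, although 7 of 9 arrays deviated most like one with their own number, a hint from the data and not the design. With the replicate block the counts were 4, 2215, 2 and 4004 and the lists 5, 8, 3 and 6 (Ex4, LQ, LQ against Ex4, both). ER-associated degradation was then not called in Ex4 (adjusted p = 0.052), and the cell cycle list was called in LQ against Ex4 (adjusted p = 0.038). Dim probe sets, where signal is near background, limit what small changes can show.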

Other observations

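The counts of genes whose groups do not overlap were chosen after the results were seen. All 6 mutant arrays lay above all 3 WT arrays for 952 of 14018 genes (6.79%) and below them for 1633 (11.6%), where chance gives 1.19% each way. These counts use the deposited scaling, in which array medians were 303.9 to 434.3 in the mutants and 506.4 to 524.4 in WT. They were not repeated under another scaling. Median centring turned the called probe sets of both mutants from 1601 higher and 2217 lower to 9039 and 697, so the balance depends on the scaling. Among the genes without overlap, named after their values were seen, C3AR1, a receptor of complement fragment C3a, was at 515 to 690 in WT and 83.2 to 178.8 in the mutants. LRG1, a secreted glycoprotein, was at 931 to 1172 and 69.6 to 357.9. VAV1, a guanine nucleotide exchange factor of blood cells, was at 76.3 to 129.9 in WT and 308.5 to 570.3 in the mutants. C3AR1 lay below the array median on all 6 mutant arrays, LRG1 on all but LQ replicate 2 and VAV1 on all 3 WT arrays, so the sizes of these differences are not measured. The probe set of TFAM that passed was 2.62-fold higher in Ex4 and 3.03-fold in LQ, while its representative probe set had 1.84-fold and 1.69-fold (adjusted p = 0.077 and 0.047). The Ex4 call of the former was lost without WT replicate 2, Ex4 replicate 3 or LQ replicate 2.

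Whether other groupings of the arrays give as many calls was tested for each contrast. For Ex4 against WT the real grouping called 4 probe sets and the other 9 splits 0 at most, and for LQ against WT 2231 and 0, in each case 1 of 10 splits, too few for a share under 0.05. For lists, 3 of 10 splits gave as many in each of these contrasts, the real counts being 6 and 8 and the highest others 9 and 8, again too few. For both mutants against WT, 2 of 100 drawn groupings gave as many as the real 3818, a share under 0.05. The other, with 4435, kept the same 3 WT arrays and mixed the mutants. The share thus shows only that the 3 WT arrays differ from the rest. WT and mutant arrays also differed in array median, GAPDH ratio and BioDn signal, so the source of the difference cannot be told. The count was 25 and 34 without WT replicate 2 or 3. For the lists of both mutants against WT, 15 of 100 groupings gave as many as the real 6, the highest being 10, so chance is not excluded.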
